A study of Homo sapiens with 11 samples.

How the data were processed

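Poly(A) RNA from 11 samples of the breast cancer lines BT483 and T47D-TamR was made into stranded libraries and sequenced in paired reads, per the labels' protocols. The reads were aligned to GRCh38, per the submitters' processing notes; the aligner, the annotation and the settings of the counting step are not given in the sources used here. The authors deposited raw counts per gene symbol for 59087 genes in each library. They also deposited log2(TPM + 1) values per library; in a check of 11517 genes, counts and TPM values in every library fitted 1 length per gene. A further deposited table of log2 TPM values for the series had been brought to nearly the same distribution in every library, as quantile normalization does. Its sorted values differed by at most 0.0101, and 27 of its gene names had turned into dates. Every later setting on deposited log2 values or log2 TPM values, limma included, used this table. The main tests used the counts. Every column used was matched to its sample by name, and 0 columns were left unmapped.

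Groups came from the sample titles. Each of the 11 groups held 1 library, so no group had replicates of its own. Total counts ran from 14637083 to 26915863 per library, and 3 counts, the floor used for values not told from 0, corresponded to between 0.112 and 0.205 CPM. Intervals for counts and ratios are exact 95% intervals (Poisson, or binomial conditional on the sum of both counts) and cover counting error only. Mitochondrially encoded genes took 9.18 to 11.5% of counts in BT483 and 6.47 to 8.61% in T47D-TamR.

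Tests on counts used edgeR 4.0.16 in R 4.3.3: TMM scaling (factors from 0.937 to 1.06), filterByExpr, a negative binomial fit with robust quasi-likelihood dispersion, and the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Knockdown and tamoxifen were coefficients of an additive fit of all 11 libraries, with the context (BT483 siRNA arm, T47D-TamR siRNA arm, T47D-TamR drug arm) as the block and VX-702 as its own coefficient; 24023 genes were tested. A fit with knockdown and tamoxifen per line gave the tests in each line and of the differences between lines, a fit with an added coefficient for the siRNA gave the siRNA difference, and a fit of the 8 siRNA libraries blocked by condition gave the line difference over 21990 genes. In these fits a group with a lone library is assumed to vary like the others. This made 9 tests across genes. Biological coefficients of variation were 0.179 in the additive fit, 0.173 in the fit per line, 0.162 in the siRNA fit and 0.179 in the line fit.

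Gene lists were tested with camera at a preset correlation of 0.01 between genes, 2-sided, adjusted over the lists with at least 5 tested members, and again with the correlation estimated from the data. The 24 lists covered estrogen response, luminal and basal identity, G1/S and G2/M cell cycle, cholesterol and fatty acid synthesis, interferon response, p53, Wnt, Notch and FOXO targets, amino acid stress under ATF4, ribosome biogenesis, ERK feedback, NF-κB and inflammation, the unfolded protein response, hypoxia and glycolysis, lysosome and autophagy, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, mesenchymal and fibroblast genes, leukocyte and endothelial genes, and the NLK and p38 pathway. Some lists share members, such as 3 between the estrogen and ERK lists. KIF23 and OAS1 are members of lists that were not analysed here, and 5 genes of ATP synthase were found under their newer symbols.

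VX-702 and control siRNA were each compared with DMSO in T47D-TamR as 1 library against 1, with no p-value: log2 differences of TMM-scaled CPM with a prior count of 2, over genes with an average of at least 5 CPM. A list's median was placed among 10000 random lists of its size matched on mean expression in 20 bins. Correlations across genes have 95% intervals from 500 bootstrap draws of genes. Where comparisons shared a control, unchanged groups were simulated against it 20 times, with the common dispersion of the additive fit for every gene. The target sites of the siRNAs, the transcript lengths and GC contents, and the 3′ UTRs searched for seed sites came from GENCODE 29 on GRCh38.

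Genes were named by a rule. NLK came first. For knockdown, tamoxifen and line these were genes with a symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and the same direction in every library against its control, the 10 highest and 10 lowest by log2 fold change, filled up to 10 with the genes of smallest p where fewer passed; the other tests took the 4 highest and 4 lowest. For the comparisons with DMSO it was the 10 highest and 10 lowest, and for lists 2 to 4 members with the largest change. ESR1, PGR, GREB1, TFF1, MAPK14, MYC and CCND1 were always given. A gene that the rule takes in is not reported here. The groups, the tests, the lists, this rule and the other settings to be tried were set before the data were examined; that a clone-based name does not count as a symbol was settled afterwards.

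The settings chosen then were DESeq2 1.42.0 (Wald test), RLE scaling, no filter (at least 1 count in all), at least 10 counts in every library, limma 3.58.1 on the deposited log2 TPM values, fits without the block, fits of only the libraries compared or of all 11, leaving out each library compared, and, for single pairs, a prior count of 0.5, no TMM scaling, the deposited log2 TPM values and at least 10 CPM. Added after seeing the data were an adjustment for transcript length and GC content (an offset per gene and library from a smooth with span 0.3), leaving out each library of a fit that lies outside the comparison, and the overlap of knockdown and tamoxifen calls under the other settings.

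The tests were tested on simulated data in which 200 genes had changed, 100 by each of the fold sizes 2 and 4. At 2-fold and 4-fold the edgeR test recovered 72 and 99% for knockdown, 74 and 99% for tamoxifen, 31 and 90% for knockdown in BT483, 45 and 92% for knockdown in T47D-TamR, 9 and 63% for its line difference, 51 and 96% for tamoxifen in T47D-TamR, 4 and 69% for its line difference, 44 and 97% for the siRNA difference and 80 and 99% for the lines. Unchanged genes called by mistake numbered between 13 and 26 per simulation, over 20963 to 23297 genes tested. As a share of the genes called, they exceeded the adjusted p threshold of 0.05 in each of these tests. For the knockdown line difference, 14 were called by mistake beside 9 and 63 changed genes recovered. For the siRNA difference, 26 were called by mistake beside 44 and 97 recovered. With the length and GC adjustment, 47 and 95% were recovered for tamoxifen in T47D-TamR, with 49 unchanged genes called by mistake against 19 without it. Those simulated counts carried no length or GC trend, so the adjustment, taken from the real libraries, itself brought a trend in. In simulated unchanged genes that carried the length and GC trends of these libraries, 10 were called without and 4 with the adjustment. A simulated list that moved was found, with 0 others called. The simulated genes varied independently, so this cannot show how the preset correlation performs on lists whose members vary together. Correlations, smooths and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.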

Results

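RNA was sequenced from 11 libraries of 2 estrogen receptor positive human breast cancer lines to follow the effect of lowering nemo-like kinase (NLK). NLK is a serine/threonine kinase related to the MAP kinases that acts on Wnt and Notch transcription factors. BT483 is a ductal carcinoma line, and T47D-TamR is a derivative of T47D kept in tamoxifen until it became resistant. Tamoxifen is an antiestrogen that competes with estradiol for the estrogen receptor. Cells of both lines were deprived of estrogen for 48 h. Each line was then transfected at 10 nM for 72 h with a pool of non-targeting small interfering RNAs (siRNAs) or with 1 of 2 siRNAs against NLK, named type 1 and type 2 in the labels. An siRNA is a short duplex that directs the cleavage of a matching mRNA. A further control siRNA culture received 0.5 µM tamoxifen. T47D-TamR cells alone were also given the solvent DMSO, 0.5 µM VX-702, or DMSO with 0.5 µM tamoxifen. VX-702 is known as an inhibitor of p38α MAP kinase (MAPK14), and the labels present it as a drug that acts on NLK. Every group held 1 library, giving 4 BT483 and 7 T47D-TamR libraries. The comparisons asked which genes NLK knockdown, tamoxifen and VX-702 alter and whether the lines and the siRNAs differ in this. They asked further whether VX-702 moves the same genes as knockdown, and how the lines differ.

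In BT483 the total counts were 16859630 with control siRNA, 14637083 with type 1, 25728513 with type 2 and 25274101 with control siRNA and tamoxifen. In the siRNA arm of T47D-TamR they were 25355025 with control siRNA, 26442260 with type 1, 23716207 with type 2 and 26849956 with control siRNA and tamoxifen. Its drug arm had 24884030 with DMSO, 25488313 with VX-702 and 26915863 with DMSO and tamoxifen. At these depths 3 counts correspond to between 0.112 and 0.205 CPM of the library total; CPM values of genes are counts scaled to library sizes with TMM factors. Intervals on counts cover counting error only, because PCR reads without molecular identifiers are not independent molecules. As groups held 1 library each, tests took the other line, the other siRNA or the other tamoxifen pair as the replicate. The labels do not say that these were separate cultures, so p-values measure only the spread between these samples.

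NLK mRNA was lower in each of the 4 knockdown libraries than in the control siRNA library of its line. In BT483 it stood at 30.0 CPM with control siRNA, 8.52 CPM with type 1 and 5.42 CPM with type 2, or 28.4% of control (95% interval 23.3 to 34.4) and 18.04% (14.9 to 21.7). In T47D-TamR it stood at 29.3 CPM with control siRNA, 10.3 CPM with type 1 and 12.2 CPM with type 2, or 35.4% (30.6 to 40.8) and 41.7% (36.2 to 47.9). The other libraries had 34.5 CPM (BT483 with tamoxifen), 29.6 CPM (T47D-TamR with control siRNA and tamoxifen), 32.8 CPM (DMSO), 28.1 CPM (VX-702) and 33.2 CPM (DMSO with tamoxifen). NLK lies on the plus strand of chromosome 17 from 28041737 to 28196381 (GRCh38, GENCODE 29). The siRNA numbered 1 in the protocol, GTCAGTAACAGATCCAAGA, matches exon 2 of 11 in the coding sequence of its protein-coding transcript, at 28122603 to 28122621. The siRNA numbered 2, GAGCTGAATTTGAAGACTA, matches the 3′ untranslated part of exon 11, at 28196045 to 28196063. Neither 19-base sequence had an exact match in the transcripts of another gene. That types 1 and 2 in the sample names are siRNAs 1 and 2 of the protocol is read from the numbering alone, and which of the suppliers' versions of siRNA 1 was used is not stated.

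**Figure D1:**
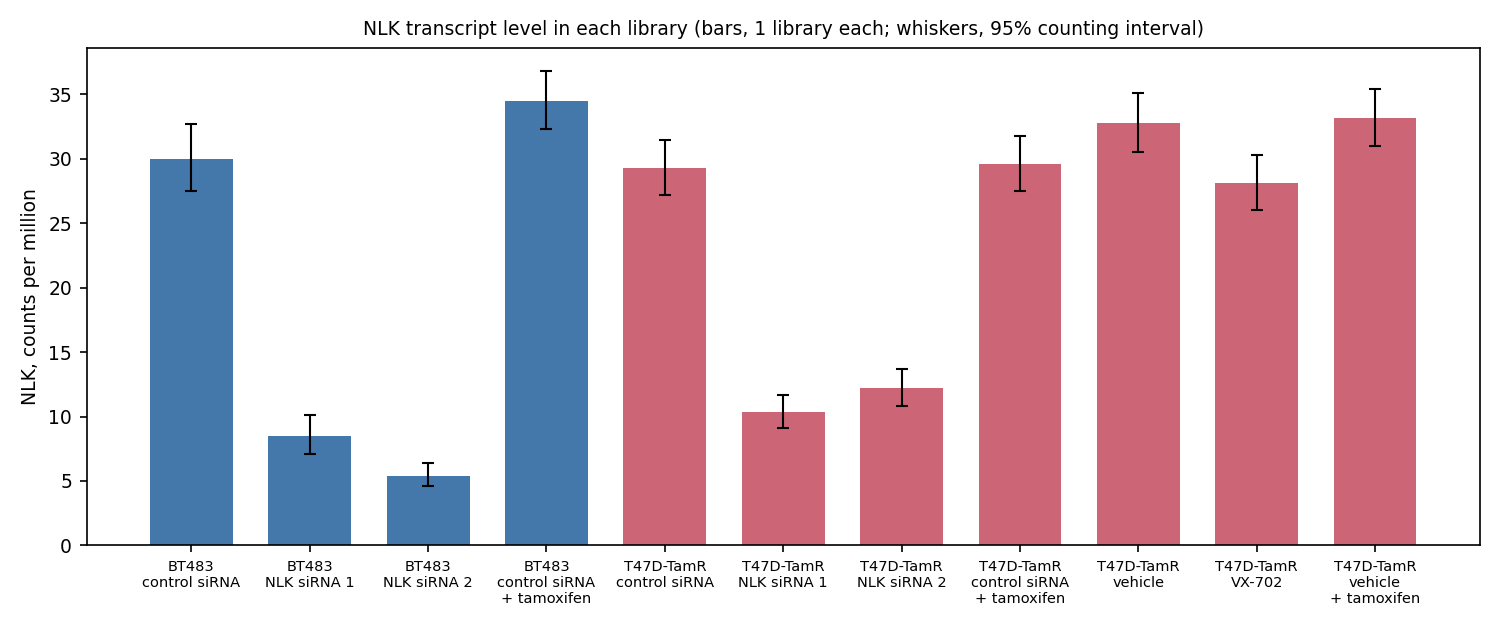
NLK level in CPM (bars) in each of the 11 libraries, with 95% intervals for counting error only. The 4 knockdown libraries sit between 5.42 and 12.2 CPM, and the 7 others between 28.1 and 34.5 CPM.

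The question of the knockdown comparison was which genes change when NLK is lowered, over both siRNAs and both lines. NLK itself fell, with a log2 fold change of -1.75 (SE 0.21, 4 knockdown against 2 control libraries, lower in 4 of 4), and was the only gene called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0308). In 10 simulations of unchanged groups this test called a mean of 1.7 genes, so a count of 1 is no more than it gives without an effect. Interferon-stimulated genes, which respond to double-stranded RNA and antiviral signalling, rose as a group. In this list 34 of 34 had positive coefficients, with a median log2 fold change of 1.05 (camera adjusted p = 2.27e-28; adjusted p = 0.379 with an estimated correlation). The leading members were IFI44L (2.21), OAS2 (2.08), IFI27 (2.03) and CMPK2 (1.84), none called alone. Genes of the G2 and M phases fell as a group, 30 of 31 being negative with a median of -0.53 (camera adjusted p = 6.05e-12; adjusted p = 0.439 with an estimated correlation). TOP2A, the topoisomerase that untangles replicated chromosomes, stood at -1.32, HMMR at -1.06, and ASPM and CENPF at -1.04.

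Genes of G1 and S phase also fell as a group, 30 of 32 being negative, with a median of -0.25 and CCNE2 (cyclin E2) at -0.62 (camera adjusted p = 0.00317; adjusted p = 0.834 with an estimated correlation). NF-κB and inflammation genes rose (median 0.47, 14 of 17 positive, camera adjusted p = 3.12e-06), led by TNFAIP3 (0.97), an NF-κB feedback inhibitor, and IRF1 (0.61). Feedback genes of ERK signalling rose (median 0.29, 18 of 20 positive, camera adjusted p = 3.52e-05), led by the phosphatase DUSP4 (0.63), SPRY4 (0.62) and PHLDA1 (0.59). So did p53 targets (median 0.17, 22 of 28 positive, camera adjusted p = 0.000158), with GDF15 at 0.74 and the cell cycle inhibitor CDKN1A at 0.63. Lysosome and autophagy genes rose (median 0.18, 19 of 24 positive, camera adjusted p = 0.000275), with GPNMB at 0.71 and NEU1 at 0.40. So did basal identity genes (median 0.33, 18 of 20 positive, camera adjusted p = 0.0319), with KRT17 at 0.74 and ID4 at 0.66. For these NF-κB, ERK, p53, lysosome and basal lists the call was lost, at an adjusted p = 0.379 with an estimated correlation. Amino acid stress genes under ATF4 rose (median 0.15, 24 of 31 positive, camera adjusted p = 0.000677; adjusted p = 0.492 with an estimated correlation), with CHAC1 at 0.99 and SESN2 at 0.50. Cholesterol synthesis genes rose by a median of 0.09 (22 of 24 positive, camera adjusted p = 0.0412; adjusted p = 0.712 with an estimated correlation). Adjusted over the list alone, 1 gene each was called in the ATF4, NF-κB and p53 lists and 0 in the interferon list.

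By line, the G1/S medians with types 1 and 2 were -0.49 and -1.002 in BT483, against 0.11 (21 of 32 higher) and -0.043 (17 of 32 lower) in T47D-TamR. The ATF4 medians were -0.093 (24 of 31 lower) and -0.079 (18 of 31 lower) in BT483, against 0.53 and 0.29 in T47D-TamR. In BT483 they were 0.017 and 0.067 for ERK feedback, -0.043 and 0.24 for lysosome, 0.0045 and 0.36 for basal and 0.0083 and 0.028 for cholesterol genes. In T47D-TamR an adjustment for transcript length and GC content, chosen after seeing the data, moved the type 1 medians from 0.17 to 0.021 for lysosome, 0.14 to 0.019 for p53, 0.24 to 0.10 for basal and 0.18 to 0.099 for cholesterol genes. With type 2 they moved from 0.33 to 0.16, 0.20 to 0.13, 0.48 to 0.33 and 0.21 to 0.12. The adjusted medians with types 1 and 2 were 0.39 and 0.26 for ATF4, 0.26 and 0.63 for ERK feedback and 0.38 and 0.92 for NF-κB genes.

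The other 14 lists were not called. Estrogen response genes were split, with 21 of 40 positive and a median of 0.02 beside a negative mean of -0.05 (camera adjusted p = 0.801). The medians of the Wnt target (0.19, camera adjusted p = 0.0552), Notch target (0.20, camera adjusted p = 0.0573) and mesenchymal or fibroblast lists (0.31, camera adjusted p = 0.0573) lay nearest to a call. The medians were 0.06 for the NLK and p38 pathway, in which NLK alone was called, 0.08 for fatty acid synthesis, 0.01 for FOXO targets and -0.00046 for hypoxia and glycolysis. They were 0.03 for leukocyte and endothelial genes, -0.08 for mitochondrially encoded genes, 0.05 for nuclear genes of oxidative phosphorylation, 0.04 for ribosome biogenesis and 0.03 for the unfolded protein response. Luminal identity genes had an adjusted p of 0.732 by camera.

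Genes with the next smallest p-values did not pass the test, although those given here were lower in 4 of 4 libraries. They included MAP3K20, a stress-activated kinase (log2 fold change -0.82, adjusted p = 0.152), FAM217B (-0.91) and DBT (-0.79, both adjusted p = 0.298). They also included the condensin subunit SMC2 (-0.92, adjusted p = 0.375), followed by GHR (-0.88) and GINM1 (-0.74, both adjusted p = 0.475), MAN1A2 (-0.70, adjusted p = 0.553) and BRCC3 (-0.67, adjusted p = 0.79). MAP3K20 was at 0.569 and 0.596 of control in BT483 and at 0.584 and 0.455 in T47D-TamR. Among estrogen targets, GREB1 had a log2 fold change of -0.45 (adjusted p = 0.885), TFF1 of -0.30 (adjusted p = 0.912) and PGR of 0.69 (adjusted p = 0.88). PGR, the progesterone receptor, stood at 100.1% of control with type 1 and at 242.7% (208.4 to 283.6) with type 2 in BT483. ESR1, the estrogen receptor gene, had -0.03 (adjusted p = 0.988), MAPK14 0.05 (adjusted p = 0.965), MYC -0.05 (adjusted p = 0.994) and CCND1 (cyclin D1) 0.14 (adjusted p = 0.947). DESeq2 called 6 genes and limma on the deposited log2 values 0, while 1331 genes had an unadjusted p under 0.05 by edgeR and 1322 by limma. The call of NLK was lost without the BT483 control siRNA (adjusted p = 0.116), BT483 type 1 (0.12), T47D-TamR control siRNA (0.373), T47D-TamR type 1 (0.138), DMSO (0.13) or DMSO with tamoxifen library (0.137). It was lost also with the length and GC adjustment (0.0908), with at least 10 counts in every library (0.144) and without the block for line (1). In all of these fits 0 genes were called, except without T47D-TamR type 1, where 1 gene other than NLK was called. There were 2 genes called without BT483 control siRNA with tamoxifen.

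**Figure D2:**
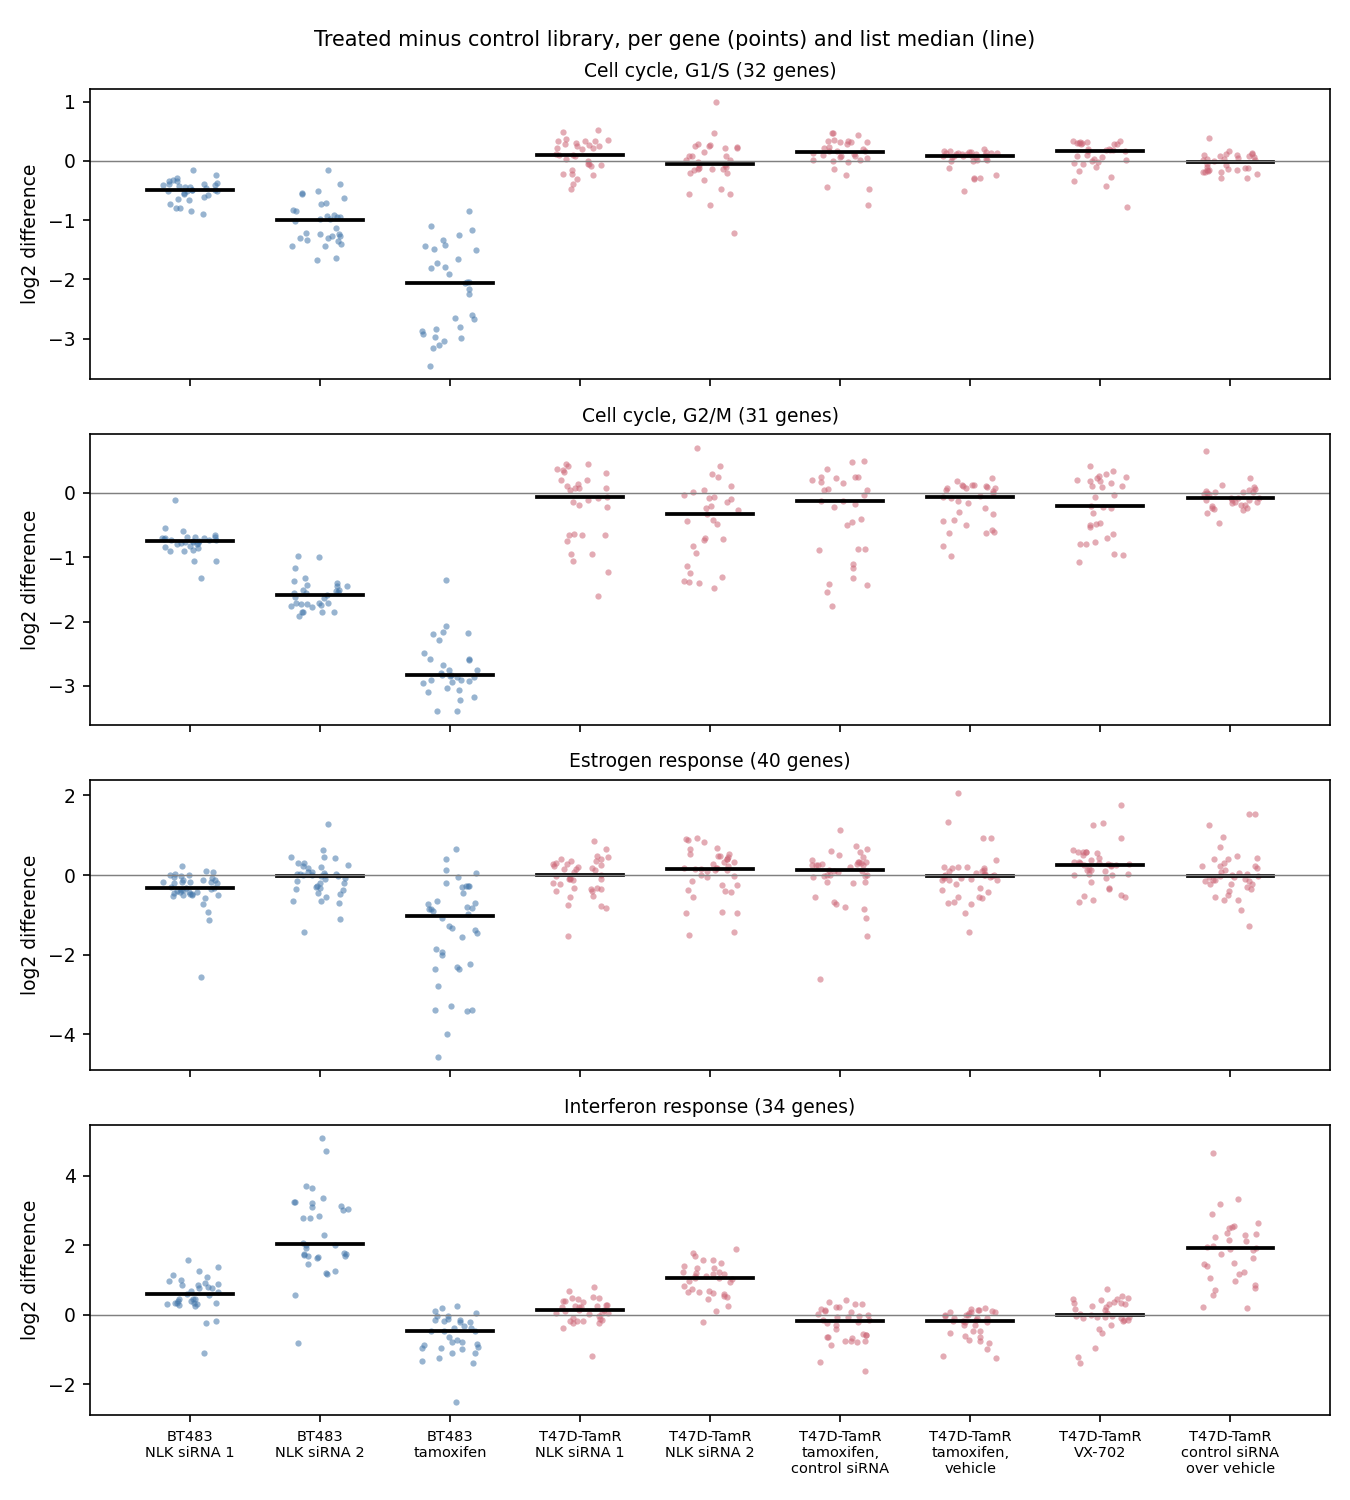
Log2 differences of single genes (points) and their median (line) in 9 pairs of libraries for the G1/S (32 genes), G2/M (31), estrogen response (40) and interferon (34) lists, computed with a prior count of 2. The G2/M median lies at -2.83 with tamoxifen in BT483 and at -0.13 and -0.06 in the T47D-TamR pairs.

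Whether knockdown acts differently in the lines was asked by fitting it per line. In BT483, G2/M genes fell as a group (31 of 31 negative, median -1.12, camera adjusted p = 2.51e-58; adjusted p = 0.342 with an estimated correlation), as did G1/S genes (32 of 32 negative, median -0.74, camera adjusted p = 4.38e-39; adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone, 28 of the G2/M and 27 of the G1/S genes were called, and 0 over all genes. TTK stood at -1.44, CCNA2 at -1.35, UHRF1 at -1.17 and CDC45 at -1.09 on the log2 scale. In T47D-TamR the G2/M median was -0.17 (camera adjusted p = 0.000189; adjusted p = 0.653 with an estimated correlation). It was -0.071 with type 1 and -0.33 with type 2, and -0.0019 and -0.27 after the length and GC adjustment. The difference between lines was -0.94 for G2/M (camera adjusted p = 9.76e-22) and -0.76 for G1/S genes (camera adjusted p = 2.91e-24), each with an adjusted p = 0.572 with an estimated correlation.

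In T47D-TamR, ERK feedback genes rose (median 0.47, 18 of 20 positive, 3 called when adjusted over the list alone), with DUSP6 and SPRY4 at 1.37 and DUSP4 at 1.28. So did NF-κB genes (median 0.68, 14 of 17 positive, 7 called when adjusted over the list alone), with TNFAIP3 at 1.04 and RELB at 0.93. The camera adjusted p was 2.78e-08 for both lists, and the adjusted p = 0.451 with an estimated correlation. ATF4 genes rose there too (median 0.33, 30 of 31 positive, camera adjusted p = 2.78e-08; adjusted p = 0.442 with an estimated correlation), with SESN2 at 0.88 and CHAC1 at 0.85. BT483 minus T47D-TamR was -0.40 for the ERK list (camera adjusted p = 2.75e-05) and -0.46 for the ATF4 list (7.82e-08), both at an adjusted p = 0.572 with an estimated correlation. It was -0.51 for the NF-κB list (0.0179; adjusted p = 0.613 with an estimated correlation). Interferon genes rose in both lines, by medians of 1.502 in BT483 (33 of 34 positive, camera adjusted p = 4.33e-28; adjusted p = 0.606 with an estimated correlation) and 0.67 in T47D-TamR (33 of 34 positive, 3.73e-06; adjusted p = 0.653 with an estimated correlation). By siRNA, type 1 and type 2 gave medians of 0.59 and 2.04 in BT483 and of 0.14 (23 of 34 higher, percentile 90.81 of random lists) and 1.05 (33 of 34) in T47D-TamR. IFI27 stood at 4.25 and IFI44L at 3.89 in BT483. The line difference of this list was 1.14 (camera adjusted p = 8.33e-10; adjusted p = 0.613 with an estimated correlation). Estrogen response genes fell by a median of 0.20 in BT483 (29 of 40 negative, camera adjusted p = 0.00069; adjusted p = 0.606 with an estimated correlation), and the line difference was -0.19 (camera adjusted p = 0.0289; adjusted p = 0.613 with an estimated correlation). In BT483 the median was -0.34 with type 1 (35 of 40 lower) and -0.018 with type 2 (21 of 40 lower).

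Mesenchymal and fibroblast genes rose in T47D-TamR by a median of 0.37 (camera adjusted p = 0.00288; adjusted p = 0.442 with an estimated correlation). Some markers of that cell type, at low levels, were higher in the transfected libraries without tamoxifen. COL1A2 was at 2.18 CPM with control siRNA, 6.56 with type 1 and 4.17 with type 2. POSTN was at 1.90, 5.23 and 3.69 CPM, against 0.345 CPM of each with DMSO and tamoxifen. COL1A2 was at 0.233 CPM in the transfected library with tamoxifen. VIM was at 1.59 CPM with control siRNA and at 0.120 CPM with DMSO.

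In BT483 NLK was the only gene called (-2.13, SE 0.26, adjusted p = 0.0198, 2 of 2 libraries lower). In T47D-TamR the only called gene was the histone pseudogene H2AFZP3 (-3.21, SE 0.41, adjusted p = 0.0396, 2 of 2 lower), whose reads may be shared with its parent gene. It had 468 counts with control siRNA, 41 and 38 with the NLK siRNAs and 31 with DMSO. NLK had -1.38 in T47D-TamR (SE 0.24, adjusted p = 0.333). TOP2A did not pass in either line, at -1.57 in BT483 (adjusted p = 0.176) and -1.35 in T47D-TamR (adjusted p = 0.333). Nor did E2F7 (-1.26) and the pseudogene PFN1P1 (-1.76) in BT483 (both adjusted p = 0.497) or DST in T47D-TamR (-0.96, adjusted p = 0.347). No gene was called for the difference between lines by edgeR, DESeq2 or limma (0 each), with unadjusted p under 0.05 for 735, 352 and 946 genes. The extremes, PFN1P1 (-2.40), ETV4 (-2.09), TK1 (-1.30) and H2AFZP3 (3.59), had an adjusted p of 1.

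Single libraries decided these counts. Without BT483 type 1, 149 genes were called in BT483, with TOP2A (adjusted p = 0.00754) and PFN1P1 (0.0352) among them, and 5 genes differed between lines. The BT483 count was 0 without BT483 type 2, T47D-TamR control siRNA, T47D-TamR control siRNA with tamoxifen, DMSO, or DMSO with tamoxifen. Without T47D-TamR type 1, 23 genes were called in T47D-TamR and 1 between lines. The T47D-TamR count was 0 without BT483 type 1, BT483 type 2, T47D-TamR control siRNA or VX-702. H2AFZP3 also lost its call without T47D-TamR type 2 (adjusted p = 0.164). Both counts were 0 with the length and GC adjustment and with at least 10 counts in every library.

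The next comparison asked how the siRNAs differ from each other, with the lines as replicates. Type 2 gave higher interferon-stimulated genes than type 1. In the list, 34 of 34 were positive, with a median of 1.35 (camera adjusted p = 3.89e-30; adjusted p = 0.54 with an estimated correlation). Of these, 20 were called when adjusted over the list alone and 2 over all genes. Among single genes BATF2 rose by 2.61 (adjusted p = 0.0123), TRIM22, an antiviral ubiquitin ligase, by 2.40 (adjusted p = 0.00631), the guanylate-binding protein GBP4 by 2.15 (adjusted p = 0.011) and WNT11 by 1.96 (adjusted p = 0.0131). With type 2, BATF2 was 7.49-fold (4.35 to 14.0) its type 1 level in BT483 and 5.17-fold (3.70 to 7.35) in T47D-TamR. NDFIP2, an adaptor of ubiquitin ligases, fell by 1.55 (SE 0.16, adjusted p = 0.00287), TMEM38B by 1.60 (adjusted p = 0.0105), CMTM8 by 1.61 (adjusted p = 0.019) and the pseudogene TWF1P1 by 2.48 (adjusted p = 0.00748), each in 2 of 2 lines. NDFIP2 was at 0.389 of control with type 2 in BT483 and 0.302 in T47D-TamR, but at 1.03 and 0.989 with type 1.

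Of the other lists, G2/M genes were lower with type 2 (median -0.54, camera adjusted p = 0.000194) and G1/S genes likewise (-0.31, 0.0127), both at an adjusted p = 0.742 with an estimated correlation. So were mitochondrially encoded genes (-0.19, 0.0174), while estrogen response (0.24, 0.0196) and ERK feedback genes (0.19, 0.0298) were higher, again at an adjusted p = 0.742 with an estimated correlation. Lysosome (0.19, 0.00854) and basal genes (0.33, 0.0218) were higher too, at an adjusted p = 0.54 with an estimated correlation, and GPNMB of the lysosome list rose by 1.21 (adjusted p = 0.011). After the length and GC adjustment, the mitochondrial medians in T47D-TamR went from 0.034 to -0.017 with type 1 and from -0.18 to 0.058 with type 2, so that type 2 was no longer the lower in that line. The estrogen response median with type 2 went there from 0.16 to 0.0017. By edgeR's test 48 genes were higher and 65 lower with type 2, 113 in all, while DESeq2 called 283 and limma on the deposited log2 values 0. The count was 0 without BT483 type 1 or T47D-TamR type 1, 58 without BT483 type 2, 198 without BT483 control siRNA and 406 without BT483 control siRNA with tamoxifen. It was 67 without T47D-TamR control siRNA, 59 without DMSO and 46 without DMSO with tamoxifen. All 8 named genes lost their calls without either type 1 library, at adjusted p from 0.0684 to 0.329. BATF2, TRIM22 and GBP4 also lost theirs without BT483 type 2 (0.0541 to 0.0965). The same held for GBP4, WNT11, CMTM8 and TMEM38B without T47D-TamR type 2 (0.0651 to 0.137), and CMTM8 without DMSO with tamoxifen (0.0601). TMEM38B lost its call with the length and GC adjustment (0.122), and CMTM8 with at least 10 counts in every library (0.0523).

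The tamoxifen comparison asked which genes the antiestrogen alters over 3 matched pairs, 1 in BT483 and 2 in T47D-TamR. TFF1, a secreted trefoil peptide and textbook estrogen target, fell by 3.46 on the log2 scale (SE 0.37, adjusted p = 0.0101), and so did SUSD3, another estrogen-responsive gene (-3.76, SE 0.43, adjusted p = 0.00538). These 2 falls were measured in the 1 BT483 pair, where TFF1 went from 680.5 to 64.5 CPM, 9.47% of control (9 to 9.96), and SUSD3 to 0.0606 of control (0.0452 to 0.0798). Their SE and adjusted p therefore take the spread from other libraries, and no second tamoxifen pair repeats the falls. In T47D-TamR, SUSD3 had 5 and 2 counts in the control siRNA pair and 3 and 1 counts in the vehicle pair. TFF1 there had 4 and 0 counts, at least 1.37-fold lower, in the control siRNA pair and 0 in both vehicle libraries. Single genes called lower, in 3 of 3 pairs each, included the kinesin KIF20B (-1.36, SE 0.20, adjusted p = 0.0334), SMC2 (-1.20, adjusted p = 0.0268), SYNE2, a nuclear envelope protein (-1.01, adjusted p = 0.0251), and RIF1, which times replication (-0.98, adjusted p = 0.0406). IL6ST, the shared receptor subunit of interleukin 6 cytokines, fell as well (-1.02, adjusted p = 0.014).

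As groups, G2/M genes fell (31 of 31 negative, median -0.80, camera adjusted p = 8.06e-31; adjusted p = 0.434 with an estimated correlation) and so did G1/S genes (32 of 32 negative, median -0.50, 2.51e-14; adjusted p = 0.461 with an estimated correlation). The BT483 pair carried these falls. The G1/S median was -2.06 in BT483, 0.15 in the T47D-TamR control siRNA pair and 0.09 in the vehicle pair. The G2/M median was -2.83, -0.13 and -0.06 in the same order. ASPM stood at -1.76, CENPF at -1.70, TOP2A at -1.53 and HMMR at -1.52, none called alone. Estrogen response genes fell (34 of 40 negative, median -0.38, camera adjusted p = 1.73e-13; adjusted p = 0.434 with an estimated correlation), with 2 members called and 9 adjusted over the list alone. Their median was -1.03 in BT483, 0.11 in the T47D-TamR control siRNA pair and -0.02 in the vehicle pair. OLFM1 stood at -1.03 and AREG at -0.85. Ribosome biogenesis genes fell by a median of 0.16 (24 of 30 negative, camera adjusted p = 2.75e-06), with NOP58 at -0.58; it was -0.42 in BT483 (29 of 30 lower), 0.016 in the T47D-TamR control siRNA pair (16 of 30 higher) and -0.080 in the vehicle pair. Mesenchymal genes had a median of -0.85 (14 of 17 negative, 0.00185), which 1 pair carried: it was -1.31 in the T47D-TamR control siRNA pair, -0.17 in the vehicle pair and -0.027 in BT483. Lysosome genes rose by a median of 0.20 (22 of 24 positive, 1.31e-05). FOXO targets rose by 0.06 (16 of 23 positive, 0.0176), with PIK3IP1 at 0.59 and CITED2 at 0.54 but RICTOR at -0.65. These last 4 lists had an adjusted p = 0.434 with an estimated correlation. Interferon genes fell (30 of 34 negative, median -0.36, camera adjusted p = 0.00148; adjusted p = 0.948 with an estimated correlation), with SAMD9 at -1.20. The other 16 lists were not called, the nearest being cholesterol synthesis (median 0.13, camera adjusted p = 0.055) and hypoxia (0.08, 0.0601).

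GREB1, a coactivator induced by estrogen, did not pass (-3.13, SE 0.43, adjusted p = 0.0527), nor did PGR (-3.22, SE 0.54, adjusted p = 0.0718), although in BT483 they stood at 10.1% (9.69 to 10.6) and 8.66% (5.62 to 12.9) of control. In T47D-TamR, GREB1 had 7 and 3 counts in the control siRNA pair and 1 and 2 in the vehicle pair, and PGR had 17 and 1 (ratio 0.0575, 0.00138 to 0.367) and 19 and 6 (ratio 0.302, 0.0988 to 0.788). MYC had a log2 fold change of -0.46 (adjusted p = 0.921) and CCND1 of -0.23 (adjusted p = 0.925), with 27.7% (24.9 to 30.7) and 47.2% (45.7 to 48.8) of control in BT483. In T47D-TamR the pairs had 1.36-fold and 0.917-fold for MYC, and 1.19-fold and 1.13-fold for CCND1. ESR1 (-0.11, adjusted p = 0.951), MAPK14 (0.11, adjusted p = 0.929) and NLK (0.09, adjusted p = 0.976) did not pass. The genes of next smallest p, which did not pass, were DEK (-0.88, adjusted p = 0.0537), PGLYRP2 (-1.81, adjusted p = 0.0544) and NRIP1, a corepressor of the estrogen receptor (-0.88, adjusted p = 0.0607). Of these genes, GREB1 was called without T47D-TamR type 2 (adjusted p = 0.0457), T47D-TamR control siRNA with tamoxifen (0.00959), DMSO (0.00667) or DMSO with tamoxifen (0.00883). PGR was called without BT483 type 1 (0.0361), BT483 type 2 (0.0141) or DMSO (0.0397). The same held for DEK without BT483 control siRNA (0.0438), BT483 type 1 (0.0454), DMSO (0.0369) or DMSO with tamoxifen (0.0357), and NRIP1 without BT483 control siRNA (0.0317).

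In all, 10 genes were called by edgeR's test, 0 higher and 10 lower, against a mean of 1.3 in 10 simulations of unchanged groups. Beside genes given above they included the pseudogene CYP2B7P and the receptor gene GFRA1, named after their values were seen. They went from 5429 to 126 and from 4469 to 443 counts in BT483 and were at or under the floor of 3 counts in T47D-TamR. Like those of TFF1 and SUSD3, these calls rest on the BT483 pair alone. With the length and GC adjustment 5 were called, and KIF20B (adjusted p = 0.527), SMC2 (0.168), SYNE2 (0.072) and RIF1 (0.084) lost their calls, RIF1 going from -0.98 to -0.69. With at least 10 counts in every library, or without the block for the pair, 0 were called, and with only the 6 libraries compared 3. DESeq2 called 84 genes and limma on the deposited log2 values 0, and 1590 had an unadjusted p under 0.05 by edgeR and 1557 by limma. The count was 0 without BT483 control siRNA with tamoxifen, 81 without BT483 control siRNA, 17 without BT483 type 1, 4 without T47D-TamR control siRNA, 6 without T47D-TamR control siRNA with tamoxifen and 19 without DMSO. SUSD3 lost its call without either BT483 library of its pair, at adjusted p of 0.239 and 0.855, and TFF1 without those (0.115 and 0.917), T47D-TamR type 2 (0.0514) or T47D-TamR control siRNA with tamoxifen (0.0542). KIF20B, SMC2, IL6ST, SYNE2 and RIF1 each lost their calls without BT483 control siRNA with tamoxifen (0.0588 to 0.0813), T47D-TamR control siRNA (0.136 to 0.305) or T47D-TamR control siRNA with tamoxifen (0.101 to 0.239). KIF20B also did so without T47D-TamR type 1 (0.0701), KIF20B and SMC2 without T47D-TamR type 2 (0.0514), IL6ST without DMSO (0.0636), and IL6ST and SYNE2 without DMSO with tamoxifen (0.0804 and 0.051). RIF1 did so without BT483 type 1 (0.0551), BT483 type 2 (0.0501), T47D-TamR type 1 (0.065), VX-702 (0.0575), DMSO (0.13) or DMSO with tamoxifen (0.173).

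Tamoxifen was then compared between the lines. In BT483 every G2/M gene was lower with tamoxifen, by a median of 2.83 on the log2 scale, and 31 of 32 G1/S genes were beyond 1 log2 unit, with a median of -2.06. The T47D-TamR pairs had medians of -0.13 and -0.06 for G2/M and 0.15 and 0.09 for G1/S genes. The difference itself was called for 166 genes by edgeR's test, 165 of them lower in BT483 relative to T47D-TamR. It took in 23 of 32 G1/S genes (median -2.20, camera adjusted p = 2.73e-80; adjusted p = 0.191 with an estimated correlation), among them CDC45 (-3.29, adjusted p = 0.00072), CDT1 (-3.25, adjusted p = 0.00331) and UHRF1 (-3.43, adjusted p = 0.00298), which load and start replication forks or maintain DNA methylation. It took in 16 of 31 G2/M genes (median -2.48, 2.6e-72; adjusted p = 0.192 with an estimated correlation), among them the mitotic kinase PLK1 (-3.20, adjusted p = 0.000743) and the kinesin KIF20A (-3.23, adjusted p = 0.0104). Adjusted over the list alone, the counts were 31 and 29.

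Estrogen response genes differed in the same direction (median -1.17, camera adjusted p = 2.63e-19; adjusted p = 0.191 with an estimated correlation), with 7 called and 17 adjusted over the list alone. They included IGFBP4 (-2.37, adjusted p = 0.00331), the EGF receptor ligand AREG (-2.12, adjusted p = 0.00137), STC2 (-2.32, adjusted p = 0.0224), MYC (-2.02, adjusted p = 0.0134) and CCND1 (-1.30, adjusted p = 0.0321), while GREB1 did not pass (-2.64, adjusted p = 0.239). In BT483 the estrogen response median was -1.03, with 36 of 40 genes lower, and in T47D-TamR it was 0.11 and -0.02. Smaller differences were called for the ATF4 list (-0.45, camera adjusted p = 8.94e-07), cholesterol (-0.42, 0.00102) and fatty acid synthesis (-0.40, 0.00349), all at an adjusted p = 0.213 with an estimated correlation. FADS2 was called in the last (-2.10, adjusted p = 0.0134). They were called also for ribosome biogenesis (-0.30, 0.00184; adjusted p = 0.334 with an estimated correlation), ERK feedback (-0.36, 0.00501; adjusted p = 0.537 with an estimated correlation) and Notch targets (-0.51, 0.0297; adjusted p = 0.512 with an estimated correlation). After the length and GC adjustment the Notch medians went from -0.18 to -0.088 in BT483, from 0.25 to 0.018 in the T47D-TamR control siRNA pair and from 0.025 to -0.054 in the vehicle pair. In the same order they went from -0.28 to -0.28, 0.17 to -0.0056 and 0.041 to -0.050 for ERK feedback, from -0.30 to -0.24, 0.28 to 0.12 and 0.054 to 0.052 for fatty acid synthesis, and from -0.42 to -0.37, 0.016 to -0.095 and -0.080 to -0.14 for ribosome biogenesis.

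The genes of most negative difference were LINC01511 (-6.43, SE 1.36, adjusted p = 0.0439), the telomerase gene TERT (-5.18, SE 1.02, adjusted p = 0.0281), the pseudogene GLDCP1 (-4.46, SE 0.78, adjusted p = 0.0133) and PDZK1, an estrogen-regulated scaffold protein (-4.16, SE 0.71, adjusted p = 0.0109). LINC01511 went from 7 to 0 counts in BT483, at least 3.54-fold lower, and TERT from 26 to 1 (ratio 0.0254, 0.000618 to 0.154). In T47D-TamR they stood at 1.13-fold and 1.04-fold their controls. PDZK1 stood at 0.0929 of control (0.0704 to 0.121) in BT483. The only gene called in the other direction, the antisense transcript AL137003.1, was named after its values were seen and had 2.62 (SE 0.56, adjusted p = 0.0463). DESeq2 called 271 genes and limma on the deposited log2 values 1. The count was 0 without T47D-TamR control siRNA, T47D-TamR control siRNA with tamoxifen or DMSO with tamoxifen, 9 without DMSO, 271 without BT483 type 2 and 250 without T47D-TamR type 2. The 4 named genes lost their calls without any of those first 4 libraries, at adjusted p from 0.0832 to 0.426. LINC01511 also lost its call without BT483 type 1 (adjusted p = 0.0578) or VX-702 (0.0562), and TERT with the length and GC adjustment (0.0817). BT483 had 1 tamoxifen pair, assumed to vary like the other groups, and no separate test was made in it.

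**Figure D3:**
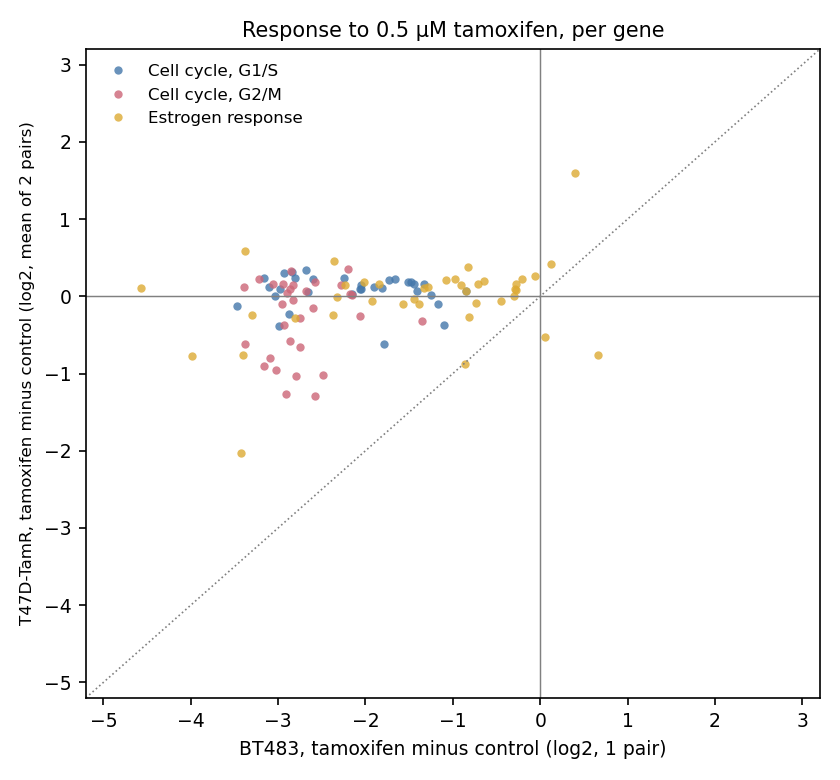
Log2 difference with tamoxifen of each G1/S, G2/M and estrogen response gene in BT483 (x axis, 1 pair) against T47D-TamR (y axis, mean of 2 pairs). The median differences between the lines are -2.20 for G1/S, -2.48 for G2/M and -1.17 for estrogen response genes.

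Within T47D-TamR, 53 genes fell and 0 rose with tamoxifen by edgeR's test. VPS13A, a lipid transfer protein (-1.30, SE 0.19, adjusted p = 0.0237), ANKRD26 (-1.30, SE 0.23, adjusted p = 0.0452), the ciliary dynein DYNC2H1 (-1.29, SE 0.20, adjusted p = 0.026) and the autophagy initiator RB1CC1 (-1.27, SE 0.20, adjusted p = 0.0298) led, each lower in 2 of 2 pairs. VPS13A was at 0.334 and 0.490 of control in the T47D-TamR pairs and at 0.965 in BT483. Estrogen response genes had a median of 0.08 (camera adjusted p = 0.931). G2/M genes fell by a median of 0.10 (camera adjusted p = 0.000812; adjusted p = 0.894 with an estimated correlation), and mesenchymal genes fell by 1.501 (0.00142). Cholesterol synthesis (0.28, 0.000483) and hypoxia genes (0.12, 0.0283) rose, and these last 3 lists had an adjusted p = 0.51 with an estimated correlation. The mesenchymal marker COL1A2 was at 2.18 CPM with control siRNA and 0.233 CPM with tamoxifen added, and VIM at 1.59 and 0.194 CPM. Members with higher levels did not fall in that pair. COL1A1 went from 44.1 to 62.7 CPM, ACTA2 from 42.6 to 48.2, FN1 from 16.8 to 18.5 and TAGLN from 18.7 to 19.6. Lysosome (0.19, 0.000812) and ATF4 genes (0.22, 0.00329) rose as well, at an adjusted p = 0.683 with an estimated correlation, and interferon genes fell by 0.20 (0.0419; adjusted p = 0.946 with an estimated correlation). The list tests did not use the adjustment for transcript length and GC content given below. With it, the G2/M median in the control siRNA pair went from -0.13 to 0.021 and in the vehicle pair from -0.065 to -0.049. In the same order, the medians went from 0.27 to 0.13 and 0.11 to 0.017 for ATF4, 0.37 to 0.18 and 0.19 to 0.12 for cholesterol synthesis, and 0.26 to 0.11 and 0.17 to 0.087 for lysosome genes. They went from 0.13 to 0.045 and 0.13 to 0.15 for hypoxia, -1.31 to -1.10 and -0.17 to -0.22 for mesenchymal, and -0.19 to -0.17 and -0.16 to -0.20 for interferon genes. The 53 genes had long and AT-rich transcripts, with a median GC content of 38.2% against 48.6% over all genes, and a median length of 9543 against 3348 bases. With an adjustment for transcript length and GC content, chosen after seeing the data, 0 of the 53 were called and 783 genes had an unadjusted p under 0.05. DESeq2 called 113 genes, and limma on the deposited log2 values 0, with 1384 unadjusted. The count was also 0 without any 1 of its own 4 libraries, 93 without T47D-TamR type 1 and 100 without T47D-TamR type 2.

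The VX-702 comparison asked what the drug alters in T47D-TamR. It set 1 library against 1, so its differences have no replicate check. The cancer-testis gene GAGE12J had 1485 counts with DMSO and 15 with VX-702 (ratio 0.0106, 0.0059 to 0.0175), a level that is uncertain because near-identical copies share its reads. STARD5, a sterol transfer protein, was at 0.326 of DMSO, the microtubule protein MAP9 at 0.363, CCDC39 at 0.380, the chromatin proteins PHIP at 0.442 and ATRX at 0.462, and UACA at 0.452. ZMAT1 was at 0.461, DYNC2H1 at 0.465 and the pseudogene EEF1DP1 at 0.160. Higher genes were PDCD2L (2.25-fold, 1.79 to 2.85), the atypical kinase MAPK4 (2.21-fold), TIMP3 (2.13-fold), and RASL10B (2.12-fold). Others were the Notch modifier LFNG (2.09-fold), the cytokine IL32 (2.09-fold), ACTA2 and SYNPO (1.99-fold each), and the multicopy SSX2B (2.19-fold) and SSX2 (2.04-fold). MAPK14 was at 108.7% of DMSO (104.3 to 113.4), NLK at 85.8% (77.4 to 95.2), and ESR1 at 96.1% (85 to 108.6). MYC was at 142.8% (119.1 to 171.4), CCND1 at 124.4% (116.3 to 133) and PGR at 60.6% (26 to 133.9). TFF1 had 0 counts in both libraries, and GREB1 was near the floor (ratio 8.37, 1.12 to 371.4).

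Estrogen response genes had a median log2 difference of 0.26 with VX-702 (29 of 40 higher), at percentile 99.99 of 10000 random lists matched on expression. The ATF4 list had 0.24 (99.86), ribosome biogenesis 0.22 (99.65), NF-κB 0.29 (99.33), Notch targets 0.28 (99.16), mitochondrially encoded genes 0.27 (99.08), hypoxia 0.20 (97.35) and basal identity 0.21 (96.4). G2/M genes lay at the other end, at -0.20 (percentile 0; 18 of 31 lower), while G1/S genes had 0.17 (94.96). Between these lay Wnt targets at 0.15 (90.52), oxidative phosphorylation at 0.18 (89.23), the NLK and p38 pathway at 0.16 (89.08) and ERK feedback at 0.14 (87.63). Next came lysosome at 0.13 (76.36), p53 targets at 0.12 (75.44), fatty acid synthesis at 0.14 (72.15), FOXO targets at 0.11 (71.59), cholesterol synthesis at 0.11 (51.24) and the unfolded protein response at 0.11 (36.77). Mesenchymal genes stood at -0.12 (21.32), interferon genes at 0.01 (18.65), leukocyte and endothelial genes at -0.48 (11.14) and luminal identity genes at 0.04 (7.03). The random lists were not matched on length or GC content. With the adjustment for these, chosen after seeing the data, the medians were 0.10 for estrogen response, 0.075 for ATF4, 0.051 for ribosome biogenesis, 0.21 for NF-κB, 0.13 for Notch, 0.27 for mitochondrially encoded, 0.11 for hypoxia, 0.11 for basal and -0.11 for G2/M genes. Wnt targets then had -0.046, luminal identity genes -0.076 and the unfolded protein response -0.037, all positive before. Cholesterol synthesis had 0.0096, p53 targets 0.047, G1/S genes 0.058, lysosome 0.049, fatty acid synthesis 0.053 and interferon genes 0.064, and mesenchymal genes -0.31. The others had 0.10 for oxidative phosphorylation, 0.098 for the NLK and p38 pathway, 0.099 for ERK feedback, 0.069 for FOXO targets and -0.68 for leukocyte and endothelial genes. In all, 10 genes were higher and 26 lower by more than 1 log2 unit, of 11732 genes with an average of at least 5 CPM. The total of 36 became 76 without TMM scaling and 11 with the deposited log2 values.

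Whether VX-702 moves the genes that knockdown moves was asked by correlating log2 differences across genes, which are not independent replicates. With no library in common, VX-702 and mean knockdown in T47D-TamR had a Pearson correlation of 0.648 (0.603 to 0.681; Spearman 0.646) over 11739 genes, 76.8% of which had the same sign. VX-702 and tamoxifen in the control siRNA pair had 0.735, the tamoxifen pairs had 0.657 with each other, and knockdown and tamoxifen in the vehicle pair had 0.469. Genes of low GC content were lower in the treated member of all these T47D-TamR pairs. The median log2 difference of the quintile of genes with the lowest GC content (median 38.7%) was -0.30 with VX-702, -0.26 with type 1, -0.32 with type 2, -0.41 with tamoxifen in the control siRNA pair and -0.15 in the vehicle pair. In the quintile with the highest GC content (62.0%) it was 0.22, 0.24, 0.25, 0.32 and 0.11 in the same order. After adjustment for length and GC content, chosen after seeing the data, the correlations were 0.387, 0.484, 0.471 and 0.204 in the order given. Pairs sharing a control had 0.727 for VX-702 and tamoxifen with DMSO (simulated with no effect 0.502; covariance 0.0472, simulated 0.0715) and 0.771 for knockdown and tamoxifen with control siRNA (simulated 0.574; covariance 0.0978, simulated 0.0704). Types 1 and 2 had 0.475 in T47D-TamR (simulated 0.496; covariance 0.068, simulated 0.0706) and 0.413 in BT483 (simulated 0.502; covariance 0.0416, simulated 0.0727). Knockdown and tamoxifen in BT483 had 0.566 (simulated 0.584; covariance 0.0829, simulated 0.0734). The simulation gave every gene the same spread between libraries, so its correlations follow from the shared control alone. Its covariance exceeded the observed one for VX-702 and tamoxifen with DMSO and for types 1 and 2 in both lines. The spread may thus have been set too wide, and these simulated values cannot decide whether such pairs share an effect. Across the lines, mean knockdown had 0.240, type 1 0.114, type 2 0.286, and tamoxifen in BT483 against the vehicle pair 0.0927. No gene was called in both the knockdown and the tamoxifen tests of edgeR (0, with 0.000416 from independent lists and 0.1 from unchanged groups against shared controls), beside 2 by DESeq2 and 0 by limma.

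**Figure D4:**
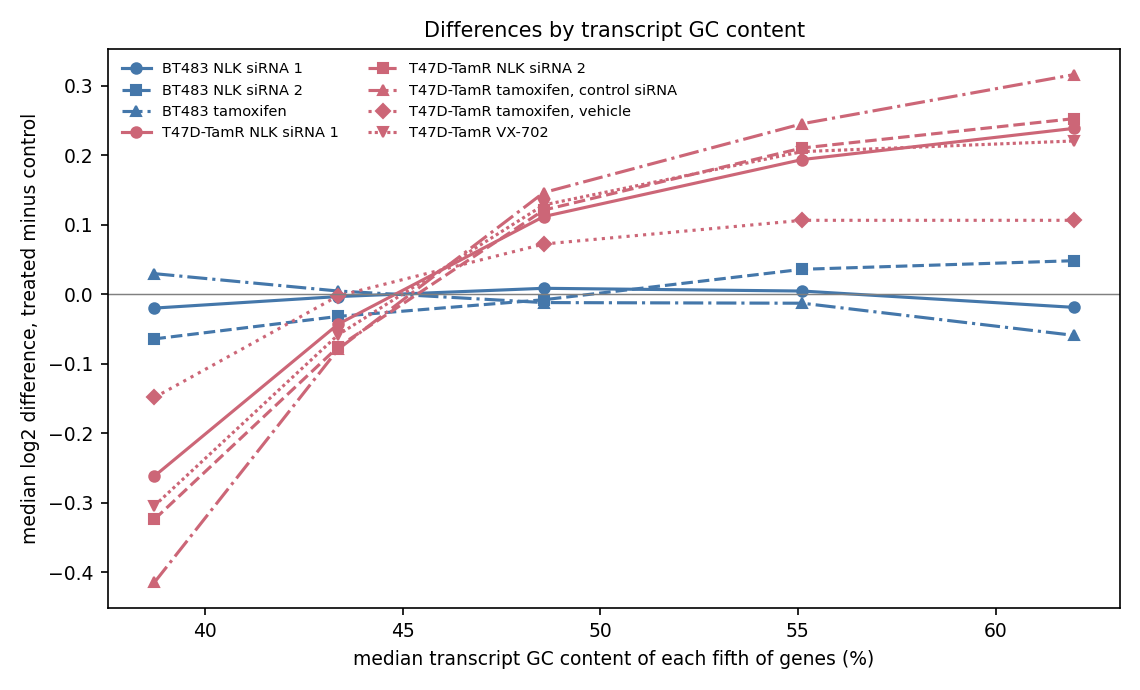
Median log2 difference of genes (y axis) by quintile of transcript GC content (x axis, percent) in 8 pairs of libraries. The lowest quintile lies between -0.41 and -0.15 in the 5 T47D-TamR pairs and between -0.06 and 0.03 in the 3 BT483 pairs.

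Control siRNA against DMSO in T47D-TamR, again 1 library against 1, gave the difference between the transfected and the drug arm, time included, since the length of the drug treatment is not stated. Interferon genes were higher in 34 of 34 members, with a median log2 difference of 1.91 (percentile 100 of random lists). IFI44L was 27.7-fold higher (18.1 to 44.4), RSAD2, which blocks viral replication, 10.2-fold, XAF1 9.65-fold and IFIT3 7.63-fold. The chemokine CCL5 was 6.64-fold higher, IFIT1 6.23-fold, OAS2 5.84-fold, IFI27 5.69-fold and IFIT2 5.15-fold, and H2AFZP3 14.95-fold. Lower genes included GAGE12J (0.0227 of DMSO), STARD5 (0.239), the cytokine feedback gene CISH (0.288), HMGN2P6 and SIGLEC6 (0.320 each), KRT15 (0.346), FN1 (0.377), NDRG1 (0.380), EEF1DP1 (0.376) and SCIN (0.378). Mesenchymal genes had a median of 0.97 (percentile 100), NF-κB genes of 0.43 (99.99), oxidative phosphorylation genes of 0.20 (99.98) and ATF4 genes of 0.14 (99.78). After the length and GC adjustment these medians were 0.85, 0.53, 0.089 and 0.11, and that of interferon genes 1.87. By more than 1 log2 unit 83 genes were higher and 30 lower, of 11741.

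Finally, the lines were compared over 4 matched conditions. BT483 expressed estrogen targets at far higher levels. TFF1 averaged 481.4 ± 298.2 CPM (SD, n = 4) against 0.0505 CPM in T47D-TamR, and 9171-fold by counts pooled over the libraries, as are the folds that follow (3929 to 28240; adjusted p = 1.3e-10). NPY1R, an estrogen-induced neuropeptide receptor, averaged 911.9 ± 333.7 CPM (SD, n = 4), 6120-fold (3647 to 11190; adjusted p = 1.32e-10). T47D-TamR in turn expressed the fatty acid transporter CD36 at 727.6 ± 162.6 CPM (SD, n = 4; ratio 0.00011, adjusted p = 4.57e-11) and the transcription factor TFAP2B at 268.1 ± 64.1 CPM (SD, n = 4), which had 0 counts in BT483 and was at least 7748-fold lower there (adjusted p = 9.44e-10). The other named genes higher in BT483 were CYP2B7P (at least 6197-fold), LONRF2 (1 count in T47D-TamR, lower limit 1993-fold), and SPATA18 (at least 1123-fold). They also included HOXD8 (at least 1098-fold), LPIN2 (at least 1002-fold), the cytokine gene IL20 (1 count, lower limit 1314-fold), DPYSL5 (at least 799.6-fold) and the chemokine receptor ACKR3 (3 counts, lower limit 1940-fold). Those higher in T47D-TamR included germline and cancer-testis genes, SSX1 (96.6 ± 8.84 CPM, SD, n = 4), CTAG2 (80.6 ± 20.5), GTSF1 (144.1 ± 47.8) and MAGEB2, and also GNAT3 (92.2 ± 15.3), SSX3, CSMD1 and LINC00221. SSX and CTAG levels are uncertain because their copies share reads.

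Estrogen response genes were higher in BT483 as a group (36 called higher and 1 lower of 40, median 2.33, camera adjusted p = 9.53e-21), led by GREB1 (11.70), OLFM1 (8.33), TFF3 (7.34) and KCNK5 (6.40). Luminal identity genes (median 1.18, 15 higher and 3 lower, 0.00204) and FOXO targets (1.06, 15 and 7, 0.03) were higher too, with ESR1 at 2.40, KLF9 at 4.79 and FOXO1 at 3.24. Lower in BT483 were the ribosome biogenesis (-1.06, 25 called lower of 30, 2.87e-05), cholesterol synthesis (-1.05, 19 of 24, 0.000104), NF-κB (-2.02, 10 of 13, 0.000227), ATF4 (-1.03, 23 of 31, 0.000476), oxidative phosphorylation (-0.96, 20 of 22, 0.000888) and basal identity lists (-1.26, 11 of 19, 0.00797). Their leading members were RRP12 (-2.58), STARD4 (-3.46), CCL2 (-8.31), PHGDH (-4.58), which starts serine synthesis, SDHB (-1.91) and KRT17 (-3.45). Each of these 9 lists had an adjusted p = 0.536 with an estimated correlation. G1/S genes (-1.86, 28 called lower of 32, camera adjusted p = 0.000104) and G2/M genes (-2.17, 26 of 31, 0.000284) were also lower in BT483, with TYMS at -3.45 and CDC20 at -3.52, at an adjusted p = 0.644 with an estimated correlation. The other 13 lists were not called. Interferon genes had a median of -0.65 with IFI27 at -6.38, mesenchymal genes -1.33, Notch targets 1.96 and p53 targets -0.29 beside a positive mean, with TP53I3 at -7.77 and CDKN1A at 2.62. By edgeR's test 7833 genes were higher and 7710 lower in BT483, of 21990 tested. MYC (2.40, adjusted p = 0.00476) and CCND1 (1.96) were among the higher.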

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

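The tests of a single unusual BT483 control library and of length and GC content given here were chosen only after the result was seen.

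The test of the tamoxifen difference between lines called 166 genes (0 without T47D-TamR control siRNA, T47D-TamR control siRNA with tamoxifen or DMSO with tamoxifen), with list medians of -2.20 for G1/S and -2.48 for G2/M genes (adjusted p = 0.191 and 0.192 with an estimated correlation). Against a single unusual BT483 control library as the whole cause, tamoxifen was lower than the mean of the 2 BT483 knockdown libraries in 63 of 63 cell-cycle genes, by a median log2 difference of -1.55 where random lists gave -0.0953 to 0.0577. Against length and GC content, 89.7% of the cell-cycle genes called for the difference (35 of 39) were called after that adjustment, with a median of -2.67 before and -2.72 after. For the smaller knockdown part of the pattern, with line differences of -0.76 for G1/S and -0.94 for G2/M genes and 63 of 63 genes below control in BT483 (median -1.06), an unusual control cannot be told apart from an effect of knockdown, since there was 1 BT483 control library without drug. An effect of tamoxifen on division that differs between the lines stays open; with 1 tamoxifen library in BT483, differences of culture density or time also stay open, as do the many other differences between the lines.

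The line differences with tamoxifen of LINC01511 (-6.43), TERT (-5.18), GLDCP1 (-4.46) and PDZK1 (-4.16) came from the same test, and the first 3 rest on 7, 26 and 29 counts in the BT483 control library. It also gave list medians of -1.17 for estrogen response, -0.51 for Notch targets, -0.45 for ATF4 genes, -0.42 for cholesterol synthesis, -0.40 for fatty acid synthesis, -0.36 for ERK feedback and -0.30 for ribosome biogenesis. With knockdown the line difference had list medians of 1.14 for interferon genes, 0.19 for FOXO targets, -0.51 for NF-κB genes, -0.46 for ATF4 genes, -0.40 for ERK feedback, -0.21 for ribosome biogenesis and -0.19 for estrogen response. The camera adjusted p was 0.0353 for FOXO targets and 0.0284 for ribosome biogenesis. None of these lists was called with an estimated correlation, the adjusted p running from 0.191 to 0.537 for tamoxifen and from 0.572 to 0.613 for knockdown.

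The tamoxifen test over both lines called 10 genes. Its 6 libraries make 10 splits, too few for a share under 0.05. In 2 of them, the real one included, as many genes were called, and the highest other called 235 genes. That split puts both libraries of each T47D-TamR pair on the same side. With the context kept as the block, its coefficient rests on the BT483 tamoxifen pair and on control against knockdown libraries. It therefore cannot judge the real split. Among splits with 1 library of each pair on each side, the real one called 10 genes and the others 4, 1 and 0. These are also too few to decide. The comparison of the lines called 15543 genes, and among 32 fitted splits of the 8 libraries 1, the real one, gave as many, while the highest other called 0. Every other split puts libraries of both lines on each side, so the line difference widens the spread and calls are hardly possible. These splits therefore cannot exclude chance as the cause of that count.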

How the results depend on the processing

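Of 1507 recomputed values of 123 named results, 1490 (98.9%) kept their direction and 17 reversed. Without a filter on low counts more genes were called: 249 for knockdown, 513 for tamoxifen, 163 and 108 for knockdown in BT483 and T47D-TamR, 21 for its line difference, 354 for tamoxifen in T47D-TamR, 502 for its line difference and 339 between the siRNAs, with 91 shared by knockdown and tamoxifen. With at least 10 counts in every library, which tests fewer genes, 0 were called for knockdown, tamoxifen, knockdown in either line and tamoxifen in T47D-TamR, and 50 between the siRNAs. DESeq2 called 6, 84, 2 and 7 (knockdown per line), 0 (its line difference), 113, 271 and 283 in the same order. Of its calls, 2 were shared by knockdown and tamoxifen. Limma on the deposited log2 TPM values called 0 for knockdown, tamoxifen, knockdown in either line, tamoxifen in T47D-TamR and the siRNAs, and 1 for the tamoxifen line difference; 1322, 1557, 1366, 1167, 1384 and 2293 genes of the first 6 had an unadjusted p under 0.05. With the length and GC adjustment, an alternative chosen after seeing the data, 0 genes were called for knockdown (1016 unadjusted), knockdown in BT483 (855) and T47D-TamR (880) and tamoxifen in T47D-TamR (783), 5 for tamoxifen and 237 between the siRNAs; the correlations of VX-702 were 0.387 with knockdown, 0.588 with tamoxifen in the vehicle pair and 0.484 in the control siRNA pair. The latter pair of correlations was 0.760 and 0.769 over genes of at least 10 CPM. Without the block for line, 0 genes were called for knockdown, and without that for the pair 0 for tamoxifen, and with only the 6 libraries compared, which leaves fewer libraries for the spread, 2 and 3. With an estimated correlation 0 lists were called for knockdown, tamoxifen or line, against 10, 8 and 11 with the preset. VX-702 against DMSO had 76 genes beyond 1 log2 unit without TMM scaling and 11 with the deposited log2 TPM values. Leaving out 1 library in turn gave 0 to 2 genes for knockdown, 0 to 81 for tamoxifen, 0 to 149 and 0 to 23 for knockdown in BT483 and T47D-TamR, 0 to 5 for its line difference, 0 to 100 for tamoxifen in T47D-TamR, 0 to 271 for its line difference and 0 to 406 between the siRNAs. The lowest and highest came without BT483 control siRNA and without BT483 control siRNA with tamoxifen (0 and 2), in the reverse order for tamoxifen (81 and 0), without BT483 type 2 and type 1 (0 and 149), T47D-TamR control siRNA and type 1 (0 and 23), BT483 type 1 (5), T47D-TamR control siRNA and type 2 (0 and 100), T47D-TamR control siRNA and BT483 type 2 (0 and 271), and BT483 type 1 and BT483 control siRNA with tamoxifen (0 and 406). The 15543 genes that differed between the lines stayed within 10610 to 16713 under the other settings and 14535 to 15363 with 1 library left out, and RLE scaling gave 1, 10, 1, 1, 0, 50, 166, 104 and 15552 genes in the 9 tests. The reversals lay in genes that no such setting called: in the knockdown test GREB1 had 0.048 and MYC 0.034 on the deposited log2 TPM values and CCND1 -0.15 without the block, and with 1 library left out CCND1 ran from -0.071 to 0.52, ESR1 from -0.18 to 0.069, MAPK14 from -0.037 to 0.10 and MYC from -0.29 to 0.41. In the tamoxifen test, with 1 library left out, CCND1 ran from -0.42 to 0.059, MYC from -1.02 to 0.085 and NLK from -0.13 to 0.24. Knockdown in BT483 and both line differences could not be fitted without BT483 control siRNA, nor the tamoxifen line difference without BT483 control siRNA with tamoxifen. Depth limits genes near the floor of 3 counts, such as GREB1 and TFF1 in T47D-TamR. Beyond the fewer genes or libraries named, the cause was not tested.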

Other observations

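The tests of length and GC content given here were chosen only after the result was seen.

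In BT483 the p38 genes MAPK11 (log2 difference 2.28) and MAPK12 (1.92) were higher than in T47D-TamR, although the NLK and p38 list as a whole had a median of 0.26 (camera adjusted p = 0.463). The chaperone genes CALR (-2.26) and HSPA5 (-2.19) were lower in BT483, while their unfolded protein response list was not called (median -0.31, camera adjusted p = 0.0661). The Wnt feedback gene AXIN2 (-1.85; list median 0.85, adjusted p = 0.109) and ACTA2 of the mesenchymal list (-5.97) were lower too. GDF15, a stress cytokine, was higher (3.72) and MT-ND1 too (1.07; mitochondrial list median 0.49, adjusted p = 0.143). The remaining lists without a call had medians of 0.65 for ERK feedback, -0.78 for fatty acid synthesis, 0.15 for hypoxia, -0.03 for lysosome and -0.11 for leukocyte and endothelial genes.

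CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, stood at 146.3% and 132.6% of control with types 1 and 2 in BT483 and at 135.4% and 209.2% in T47D-TamR, while cyclin D1 was at 89.3% and 76.7% in BT483 and at 127.9% and 144.4% in T47D-TamR. NLK itself was lower with type 2 than with type 1 in BT483 (0.636-fold, 0.499 to 0.81), and in T47D-TamR the ratio was 1.18 (0.992 to 1.40).

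In every treated T47D-TamR library transcripts of low GC content were lower than in its control, with Spearman correlations of GC content and log2 difference across genes of 0.719, 0.480, 0.644, 0.543 and 0.520 for tamoxifen in the control siRNA and vehicle pairs, VX-702, type 1 and type 2, against -0.075 to 0.135 in the BT483 pairs. Against the mean of the 7 T47D-TamR libraries, the correlation was -0.660 in control siRNA and -0.390 in DMSO. It was 0.0126 with type 1, 0.147 with type 2 and 0.0754 with DMSO and tamoxifen. It was 0.507 with VX-702 and 0.469 with control siRNA and tamoxifen. Relative to that mean the trend thus lay in both controls as well as in treated libraries. Both types and tamoxifen in the control siRNA pair share 1 control library. GC content and length are a candidate explanation for the 53 T47D-TamR tamoxifen genes: 0 of 53 were called after that adjustment, because their median log2 fold change went from -1.07 to -0.717 while the median SE went from 0.179 to 0.151, and 53 of 53 were lower before and after. In a simulation of unchanged genes that carried these trends, 10 genes were called without the adjustment, 6 of them lower. The trends as simulated thus gave fewer calls than the 53 observed. A bias of the libraries acting on every RNA class cannot be told apart from a change in the cells, since the correlation among 3099 noncoding and pseudogene transcripts was 0.299 (0.269 to 0.332), below the 0.687 of protein-coding genes yet above 0. Nor can an effect of depth: over 7 T47D-TamR libraries the total count and the GC trend had rho 0.25 (exact permutation p = 0.595) and r 0.267 (exact permutation p = 0.558), and r was 0.592 without the 2 libraries farthest from the median. The likeness of VX-702 to knockdown and to tamoxifen rests in part on this trend, as the lower correlations after adjustment show, and a common control effect or a shared response of the cells stays open.

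The NLK siRNAs gave 113 genes that differed between them, and seed matches may account for part of these, because an siRNA can repress transcripts whose 3′ UTR matches bases 2 to 8 of its guide. Genes with the type 2 seed site GAAGACT were lower with type 2, by a mean of -0.145 on the log2 scale (SE 0.0103, 1389 of 10992 genes), and 0 of 419 heptamers of like composition were as low; genes with the type 1 site ATCCAAG were shifted the other way by 0.0663 (SE 0.0107), with 3 of 419 as high. Of the lower genes with an annotated 3′ UTR, 77.2% (44 of 57) carried the type 2 site against 12.6% of all genes searched, and 32.6% of the higher genes (15 of 46) carried the type 1 site against 9.93%. Against length and GC content, 92.0% (104 of 113) were called after the adjustment. Depth of NLK knockdown had been predicted to turn the sign between lines, and the siRNA difference correlated at 0.253 (0.224 to 0.279) between BT483 and T47D-TamR. This cannot decide on depth. The NLK ratio of type 2 to type 1 in T47D-TamR, 1.18 (0.992 to 1.40), had an interval that included 1. Seed effects shared by the lines would also give a positive correlation. Seed sites among the interferon genes were not counted, and whether their higher levels with type 2 follow from its sequence or its batch stays open.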
